A study of Arabidopsis thaliana with 12 samples.

How the data were processed

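The series measured mRNA in Arabidopsis thaliana seedlings of 4 genotypes with 3 libraries each: wild-type Col-0, the DPB2-overexpressing lines DPB2oe1.11.5 and DPB2oe12.1.5, and the mutant abo4-1. The labels put every library at growth stage 1.02 on 0.5x MS medium at 20 °C, 65% humidity and 16 h of light, with no treatment. The titles of the DPB2oe1.11.5 libraries write the line with another last digit than their source and genotype labels do, and the genotype label is used here. The labels do not say whether replicates were grown separately, at which hour they were harvested, or which libraries were sequenced together.

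The libraries were stranded, single-end and sized to 230 bp after mRNA selection, and were read on an Ion Torrent Proton. The deposited values are raw read counts per locus and library, without scaling. Per the file headers, reads that mapped to several places were removed before counting, and in all 12 libraries the sum of the counts equalled the mapped reads minus the removed ones. Mapping was against TAIR10 per the submitters' processing notes, and the aligner and counting tool are not given in the sources used here. Of the 33602 loci, 32835 (97.7%) matched the TAIR10.1 annotation, which supplied coordinates, symbols and biotypes. Removal of reads with several hits lowers the counts of near-identical genes such as the H3.1 and H4 histones, LHCB1 and RBCS, so their values are less certain.

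Counted reads per library were 29456111, 10902547 and 19989373 in Col-0, 17380272, 19595776 and 14247786 in DPB2oe1.11.5, 12205407, 14067962 and 13990674 in DPB2oe12.1.5, and 18877014, 13930653 and 11587683 in abo4-1, in replicate order. Mapped reads made up 90.3% to 95.6% of all reads, and removed multiple hits 2.09% to 3.01% of the mapped ones. No pair of libraries of 1 group was a copy of another: Pearson correlations of log2 values within groups ran from 0.953 to 0.985. Replicate numbers were taken to pair the libraries of 2 groups where the deviations from the group means correlated above 0.1 in all 3 pairs of the same number. This held for DPB2oe1.11.5 and abo4-1 (0.137, 0.552 and 0.348 in replicate order), while the labels give no shared batch or day. Replicates 1 and 3 also correlated across numbers: 0.313 for DPB2oe1.11.5 replicate 1 with abo4-1 replicate 3, and 0.132 for replicate 3 with replicate 1. In both groups replicate 2 had the highest LHY level. Meeting the rule therefore does not show that replicates 1 and 3 pair by number.

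Counts were analysed in R 4.3.3 with edgeR 4.0.16. Loci passing filterByExpr by group (19924) were scaled by TMM, and 1 quasi-likelihood model with a mean per genotype was fitted to all 12 libraries (glmQLFit with robust estimation, glmQLFTest). The common biological coefficient of variation was 0.226. Adjusted p values are Benjamini-Hochberg values over all genes tested in a comparison, and genes under 0.05 were called, with no fold threshold. CPM values are counts per 1000000 counted reads scaled by TMM, given as mean ± SD over 3 libraries, and fold changes are log2 values ± SE of the model.

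The choices of test, gene lists, naming rule and other settings to try were made before the data were examined. The 17 gene lists, drawn from textbook knowledge, were Pol epsilon subunits, DNA damage response, DNA replication, G2/M cell cycle, G1/S cell cycle, CDK inhibitors and endocycle, H3.1 and H4 histones, meiotic recombination, ABA response, salicylic acid and defence, flowering and homeotic genes, photosynthesis, root tissue markers, seed storage, heat shock, flavonoid and anthocyanin, and circadian clock. Each was tested with camera in limma 3.58.1 on voom weights with a preset correlation of 0.01, adjusted over the 17 lists of a comparison, and again with an estimated correlation and with fry. Camera on the direct contrasts between mutants was added after the data were seen.

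Named genes followed a rule. It took the Pol epsilon subunits and GL1, and the 6 largest rises and 6 largest falls among called genes whose 3 libraries all lay on 1 side of the 3 Col-0 libraries and whose higher mean was at least 10 CPM. From each called list it took up to 4 called members with the lowest adjusted p, and between mutants the 3 largest rises and 3 largest falls. Any other gene named was chosen after its values were seen.

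Shares of organelle reads and of the 10 most abundant genes were compared with Col-0 by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Called genes were counted in windows of 1 Mb and 2 Mb with hypergeometric tests. Overlaps were set against independent lists and against 20 draws in which all 12 libraries were simulated without changes. There the groups shared simulated Col-0 libraries, and each gene was drawn independently. Counts of 3 served as the floor for genes at 0, and 95% intervals of ratios cover counting error only.

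The settings chosen in advance for comparison were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a mean of at least 1 CPM, the replicate number as a block, only the libraries of the compared groups, a threshold of 0.01, glmTreat against a 1.5-fold change, removal of organelle genes, and each replicate left out in turn. A clock score as covariate, a run without the 4 libraries of highest LHY, the block in the list tests between mutants and the Pol epsilon list without DPB2 were added after the data were seen. On simulated data, 4-fold changes were recovered in 90.9%, 86.4% and 78.8% of genes, 2-fold changes in 34.3%, 40.3% and 28.4%, and 1.5-fold changes in 2.99%, 2.99% and 0% for DPB2oe1.11.5, DPB2oe12.1.5 and abo4-1 against Col-0. The simulations gave 7, 10 and 7 false calls, and for abo4-1 against Col-0, where lists were simulated, 0 of 16 unchanged ones were called. Genes were simulated independently, so this does not test lists whose genes move together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.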

Results

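The transcriptomes of 12 seedling libraries were compared, with 3 libraries per genotype and 10902547 to 29456111 counted reads per library. DPB2 is a regulatory subunit of DNA polymerase epsilon, the enzyme of leading-strand replication, and is overexpressed in the lines DPB2oe1.11.5 and DPB2oe12.1.5. The mutant abo4-1 carries an allele of POL2A, the catalytic subunit. The title of the series asks which transcripts change when this polymerase is deficient. The p values of single genes measure the spread between libraries only, since the labels do not say whether replicates were grown separately. Camera sets list members against the other genes, and the window tests set called genes against all tested ones. Camera with the preset correlation of 0.01 gives too low a p where members move together more than that. In DPB2oe1.11.5 against Col-0 the estimated correlation was 0.126 for DNA damage and 0.346 for G2/M genes.

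DPB2 (AT5G22110, chromosome 5, 7330825 to 7334282 in TAIR10.1) rose from 2.90 ± 1.195 CPM (SD, n = 3) in Col-0 to 113 ± 6.54 CPM in DPB2oe1.11.5 and 115 ± 4.17 CPM in DPB2oe12.1.5. The log2 fold changes were 5.25 ± 0.24 (SE; adjusted p = 1.76e-07) and 5.27 ± 0.24 (adjusted p = 1.72e-07), and all 3 libraries of each line lay above all 3 of Col-0. In abo4-1 its level was 4.05 ± 0.552 CPM, a log2 fold change of 0.44 that did not pass the test (adjusted p = 0.687). POL2A (AT1G08260, chromosome 1, 2588854 to 2606892) measured 16.4 ± 0.836 CPM in Col-0, 29.5 ± 4.64 in DPB2oe1.11.5, 21.0 ± 5.05 in DPB2oe12.1.5 and 25.3 ± 1.15 in abo4-1. It rose in DPB2oe1.11.5 (log2 fold change 0.84 ± 0.17, adjusted p = 0.0453) and did not pass in DPB2oe12.1.5 (0.35, adjusted p = 0.325) or abo4-1 (0.62, adjusted p = 0.177). The series describes abo4-1 as a knock-out, yet its POL2A transcript was not lower than in Col-0, and transcript levels do not show whether the protein works. The POL2A call in DPB2oe1.11.5 ended when any Col-0 library or DPB2oe1.11.5 replicate 1 or 3 was left out, with log2 fold changes of 0.76 to 0.98 over the 6 libraries left out. The subunit genes DPB3-1 and DPB4 were not called in any comparison with Col-0, and POL2B was not measured above the filter.

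**Figure D1:**
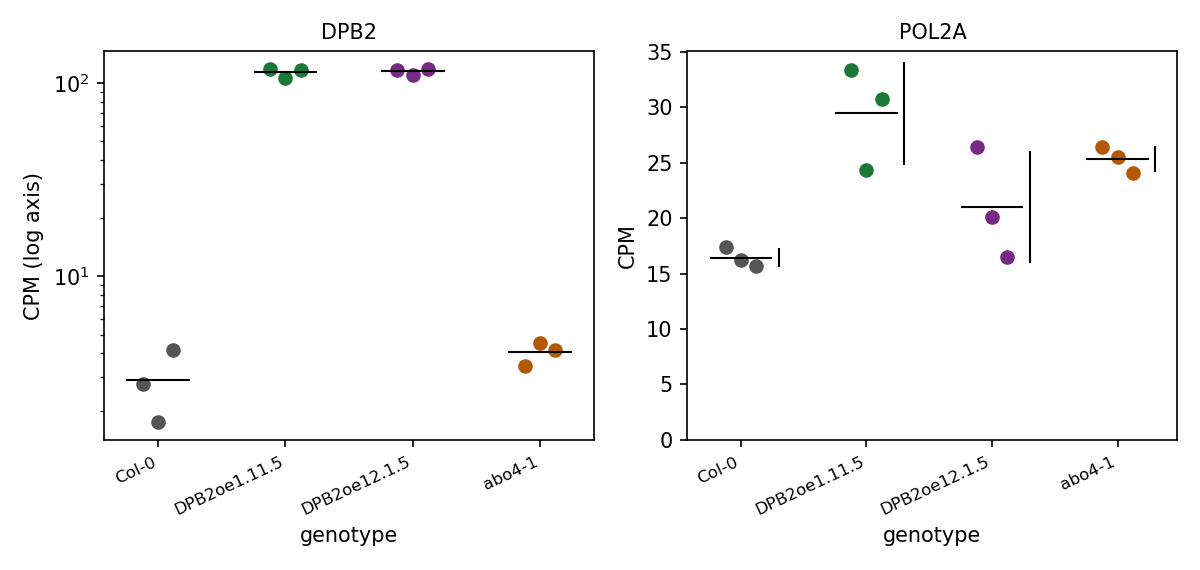
Transcript levels of DPB2 (log axis) and POL2A in CPM for each of the 12 libraries, grouped by genotype, with lines for the means and, for POL2A, bars for the SD of 3 libraries. The DPB2oe lines lie at 113 and 115 CPM of DPB2 on average, against 2.90 in Col-0.

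Libraries of the same genotype differed in time-of-day transcripts. LHY, a morning-expressed clock gene, reached 217 CPM in DPB2oe1.11.5 replicate 2, 202 and 197 CPM in DPB2oe12.1.5 replicates 1 and 2, and 173 CPM in abo4-1 replicate 2. The other libraries ranged from 3.97 to 48.1 CPM, so that no Col-0 library was among the 4 highest. PRR5, an evening-phased clock gene, ran the opposite way, from 0.279 CPM in abo4-1 replicate 2 to 51.8 CPM in abo4-1 replicate 3. The first principal component took 29.1% of the variance, and these 4 libraries lay at its positive end. Without these 4 libraries, a run chosen after the data were seen, 925 genes were called in DPB2oe1.11.5, 47 in DPB2oe12.1.5 and 148 in abo4-1 against Col-0, and the DNA damage list passed in all 3 with the preset correlation (adjusted p = 6.84e-12, 0.00117 and 9.93e-33). That run leaves 1 DPB2oe12.1.5 library, assumed to vary like the other groups, and with all 12 libraries this list did not pass in DPB2oe12.1.5 with an estimated correlation (adjusted p = 0.0787).

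**Figure D2:**
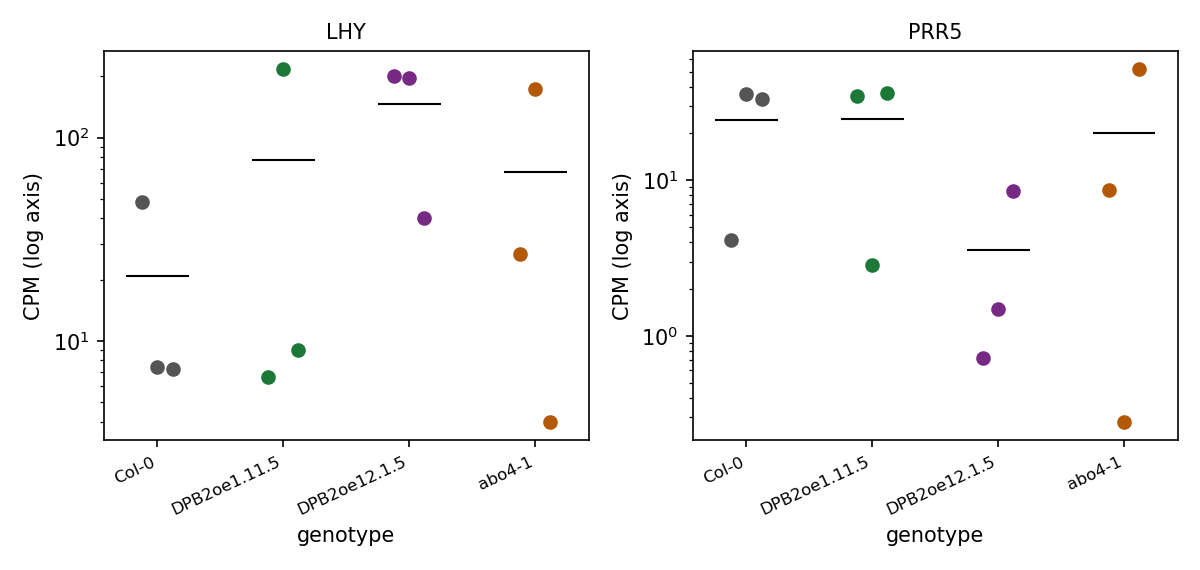
Levels of clock genes in CPM (log axis) in each of the 12 libraries, grouped by genotype, with lines for the means. LHY lies at 173 CPM or more in 4 libraries, none of them of Col-0.

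The comparison of abo4-1 with Col-0 asks how the line that carries the POL2A allele differs from wild type. Genes of the DNA damage response rose in abo4-1: SMR7, an inhibitor of cyclin-dependent kinases, went from 1.09 ± 0.474 to 23.6 ± 5.26 CPM (log2 fold change 4.39 ± 0.31, adjusted p = 7.43e-06). The repair genes PARP2 (2.61 ± 0.18), GMI1 (2.53 ± 0.18) and BRCA1 (2.27 ± 0.15) rose with it, each at an adjusted p of 7.43e-06 or less. The floral genes SEP1, SEP2 and SEP3 also rose. In all, 156 genes were called, of which 113 rose and 43 fell, and 1619 genes had an unadjusted p under 0.05.

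Of the 30 measured DNA damage genes, 17 rose, 0 fell and 13 did not pass, and 21 rose when adjusted over the list alone. The list median was 1.16 (adjusted p = 1.93e-39). Of 27 G2/M genes, which act in mitotic entry and division, 5 rose (16 adjusted over the list alone), with a list median of 0.65 and adjusted p = 1.21e-24. Examples were CDKB1;2 (1.29 ± 0.25), CDKB1;1 (1.16 ± 0.23), CDKB2;1 (0.90 ± 0.15) and CYCB1;4 (0.87 ± 0.16). Of 42 DNA replication genes, 3 rose (7 adjusted over the list alone): CDC45 (1.07 ± 0.17), RNR1, a ribonucleotide reductase subunit (1.05 ± 0.16), and POLD4 (0.87 ± 0.17). Their list median was 0.26 (adjusted p = 1.23e-10, but adjusted p = 0.0701 with an estimated correlation). Of 16 G1/S genes, CYCD3;1 rose (0.66 ± 0.13; 3 adjusted over the list alone; list median 0.22, adjusted p = 3.48e-05).

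Of 11 meiotic recombination genes, DMC1, the meiotic recombinase, rose (1.23 ± 0.15, adjusted p = 0.00104), and 6 rose when adjusted over the list alone (list median 1.196, adjusted p = 4.11e-06). Of 12 flowering and homeotic genes, SEP2 (3.39 ± 0.57), SEP1 (3.21 ± 0.65) and SEP3 (2.09 ± 0.30), which specify floral organs, rose. Adjusted over the list alone, 5 rose and 1 fell (list median 0.69, adjusted p = 7.95e-06). The Pol epsilon list had a median of 0.39, with 0 of 4 members called and 1 adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.0992 with an estimated correlation). With an estimated correlation, the DNA damage, G2/M, G1/S, meiotic and flowering lists held. The other 10 lists did not pass (adjusted p from 0.0731 to 0.898). Among them, the ABA list had a median of -0.01 with a test direction up, and the clock list a median of 0.13 with a test direction down.

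The largest changes were ranked within the naming rule's limits, which are separate libraries and a higher mean of at least 10 CPM. Among them, MRD1 rose by 6.49 ± 0.49, AT5G60250 by 4.89 ± 0.33, HDA18, a histone deacetylase, by 3.03 ± 0.30, AT1G11070 by 2.92 ± 0.38 and the thymidine kinase TK1a by 2.84 ± 0.19. Within these limits the largest falls were in AT2G33850 (-3.01 ± 0.36), ESM1 (-2.71 ± 0.22), which acts in glucosinolate breakdown, and GL2 (-2.16 ± 0.20), a regulator of trichome and root hair fate. Outside them other called genes fell further, among them AT5G33370 (-5.33) and GLC (-4.73). PRP2 (-1.64 ± 0.27), the fatty acid hydroxylase CYP86A4 (-1.54 ± 0.26) and AT5G35935 (-1.45 ± 0.23) fell too. GL1, the trichome regulator, had 7 counts in abo4-1 and 45 in Col-0, a log2 fold change of -2.15 ± 0.78 that did not pass (adjusted p = 0.424).

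Leaving out any 1 of the 6 libraries lowered the 156 calls by over 1.5 times, to 65, 72 and 94 without Col-0 replicates 2, 3 and 1 and to 87, 80 and 79 without abo4-1 replicates 1, 2 and 3. Of the 27 named genes called, 16 kept their call in all 6 of these runs, among them SMR7, BRCA1, PARP2, GMI1, DMC1, SEP3 and RNR1, while 6 lost it in all 6 (POLD4, CYCB1;4, CDKB1;2, CDKB1;1, CYCD3;1 and SEP1), and the Pol epsilon list lost its call without Col-0 replicate 2 (adjusted p = 0.111) or abo4-1 replicate 2 (0.135), and without the 4 libraries of highest LHY (0.106).

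**Figure D3:**
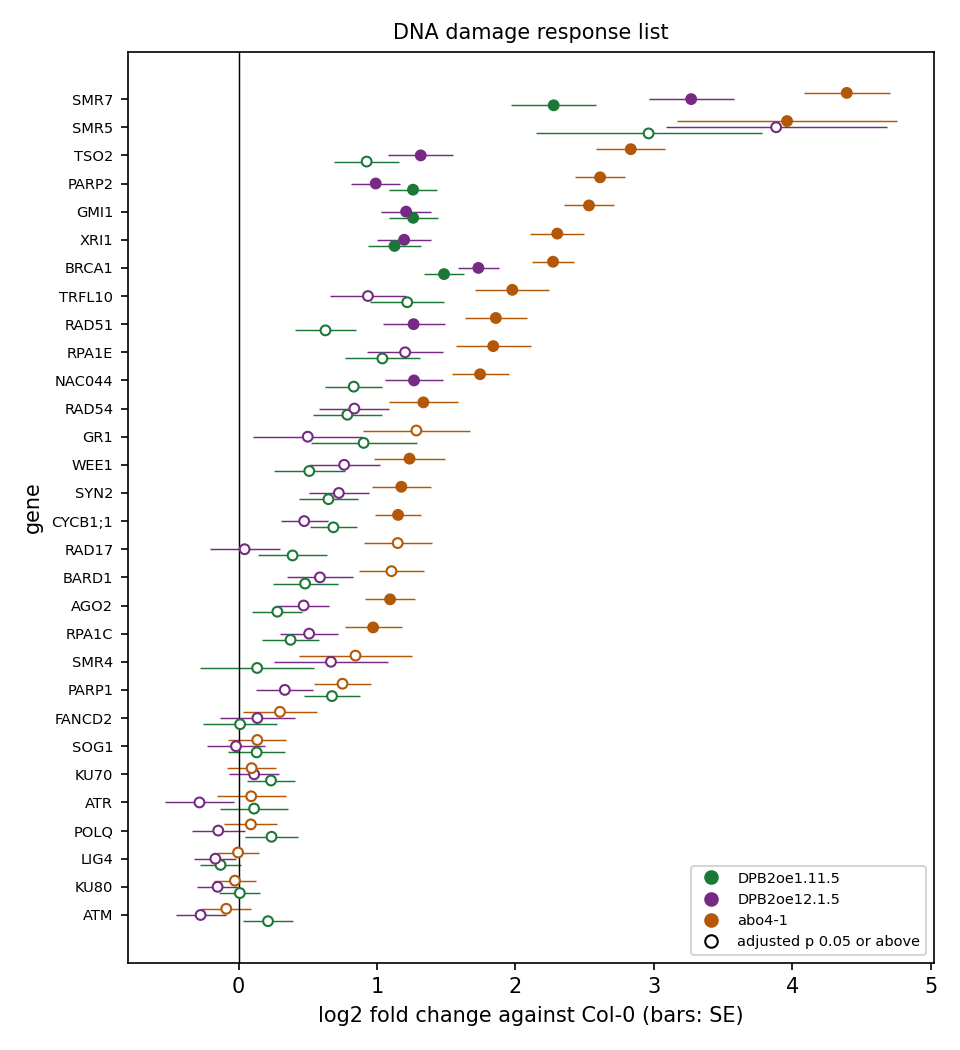
Log2 fold changes of the measured DNA damage response genes against Col-0 in the 3 mutant genotypes, with bars for the SE. Filled points passed an adjusted p of 0.05: 5 of 30 in DPB2oe1.11.5, 8 in DPB2oe12.1.5 and 17 in abo4-1.

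The comparison of DPB2oe1.11.5 with Col-0 asks how a line with an excess of DPB2 transcript differs from wild type. Besides DPB2, the DNA damage genes SMR7 (2.28 ± 0.31), BRCA1 (1.48 ± 0.15), GMI1 (1.26 ± 0.18) and PARP2 (1.26 ± 0.17) rose, as did TK1a (1.47 ± 0.19). The floral repressors MAF5 (2.79 ± 0.42) and MAF4 (1.58 ± 0.25) rose. The pseudogene AT5G33251 (chromosome 5, 12499072 to 12500433) rose from 3 counts in Col-0 to 1895 in DPB2oe1.11.5. In all, 141 genes were called, of which 35 rose and 106 fell, and 2974 had an unadjusted p under 0.05.

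Of 30 DNA damage genes, 5 rose and 0 fell, and 15 rose when adjusted over the list alone (list median 0.64, adjusted p = 2.57e-13). Of the 4 Pol epsilon genes, DPB2 and POL2A rose, 2 adjusted over the list alone (list median 0.47, adjusted p = 0.000427). This list holds the overexpressed DPB2 itself. The other 3 genes, POL2A among them, did not pass as a list with camera (median 0.09, adjusted p = 0.213), while fry gave an unadjusted p of 0.00844. Of 12 flowering and homeotic genes, MAF4 and MAF5 rose (4 adjusted over the list alone; list median 0.58, adjusted p = 0.00114). The 16 G1/S genes were shifted up as a list without a called member, also when adjusted over the list alone (median 0.30, adjusted p = 0.000175). The DNA damage, flowering and G1/S lists held with an estimated correlation (adjusted p = 0.0277 for each).

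Of 42 DNA replication genes, RNR1 rose (0.80 ± 0.16), and adjusted over the list alone 4 rose and 1 fell. Their median was 0.33 (adjusted p = 5.19e-09, but adjusted p = 0.101 with an estimated correlation). Of 27 G2/M genes, 0 were called and 13 rose when adjusted over the list alone (median 0.43, adjusted p = 7.39e-11, but adjusted p = 0.101 with an estimated correlation). Photosynthesis genes were lower as a list: 0 of 18 were called, and 12 fell when adjusted over the list alone. Their median was -0.70 (adjusted p = 1.36e-09, but adjusted p = 0.0934 with an estimated correlation). Of 17 root markers, EXPA7, a root hair expansin, fell (-1.94 ± 0.39, adjusted p = 0.0409), and 6 fell when adjusted over the list alone. Their median was -0.51 (adjusted p = 0.000384, but adjusted p = 0.107 with an estimated correlation). Of 18 ABA response genes 0 were called, also when adjusted over the list alone (median -0.36, adjusted p = 0.0401, but adjusted p = 0.562 with an estimated correlation). With fry, which does not set the members against other genes, DNA replication, G2/M and root markers passed (adjusted p = 0.0136 for each). Photosynthesis passed it too (0.00869), while ABA response did not (0.424). The other 8 lists did not pass (adjusted p from 0.0624 to 0.855).

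With separate libraries and a higher mean of at least 10 CPM, the largest falls were in U3D, a U3 small nucleolar RNA (-2.91 ± 0.36), AT1G67865 (-1.87 ± 0.34), AT3G61980 (-1.75 ± 0.29), AT5G44550 (-1.69 ± 0.31), the basic chitinase HCHIB (-1.63 ± 0.25) and the copper chaperone CCH (-1.58 ± 0.14). Outside these limits other called genes fell as far, among them AT2G47880 (-1.97). GL1 did not pass (0.25 ± 0.59, adjusted p = 0.884).

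Leaving out any 1 library moved the 141 calls by over 1.5 times, to 21, 286 and 26 without DPB2oe1.11.5 replicates 1, 2 and 3 and to 63, 38 and 32 without Col-0 replicates 1, 2 and 3. Of the 18 named genes called, 8 kept their call in all 6 runs (DPB2, TK1a, SMR7, CCH, PARP2, BRCA1, GMI1 and AT5G33251), while EXPA7 and AT1G67865 lost it in all 6, and the ABA list lost its call without Col-0 replicate 2 (adjusted p = 0.216), Col-0 replicate 3 (0.431) or DPB2oe1.11.5 replicate 2 (0.103), and without the 4 libraries of highest LHY (0.0694).

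The comparison of DPB2oe12.1.5 with Col-0 asks the same of the other DPB2oe line. SMR7 (3.27 ± 0.31), BRCA1 (1.73 ± 0.15), GMI1 (1.21 ± 0.18) and XRI1, a gene induced by X-rays (1.196 ± 0.19), rose. The floral repressors MAF4 (1.71 ± 0.25) and FLC (1.33 ± 0.26) rose, and MIOX4, a myo-inositol oxygenase, rose by 5.08 ± 0.44. The embryo genes PAP85 (3.41 ± 0.60) and EM6 (2.57 ± 0.38) rose, and the myrosinase TGG2 fell (-1.71 ± 0.14). In all, 85 genes were called, of which 40 rose and 45 fell, and 3322 had an unadjusted p under 0.05.

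Of 30 DNA damage genes, 8 rose and 0 fell, and 18 rose when adjusted over the list alone. Their median was 0.63 (adjusted p = 2.27e-10, but adjusted p = 0.0787 with an estimated correlation). Of 4 Pol epsilon genes, DPB2 rose, 1 adjusted over the list alone (median 0.33, adjusted p = 0.00567, and adjusted p = 0.0787 with an estimated correlation), and without the overexpressed DPB2 the list did not pass (adjusted p = 0.525). The 16 G1/S genes had 0 called members, also when adjusted over the list alone (median 0.30, adjusted p = 0.00444, and adjusted p = 0.0787 with an estimated correlation). Of 12 flowering and homeotic genes, MAF4 and FLC rose, and adjusted over the list alone 4 rose and 1 fell. Their median was 0.13 (adjusted p = 0.0192, and adjusted p = 0.0987 with an estimated correlation). With fry, which does not set the members against other genes, 4 lists passed: Pol epsilon, DNA damage (adjusted p = 0.00111), G1/S (0.00779) and flowering. With an estimated correlation, none of the 17 lists passed in this comparison. The Pol epsilon and G1/S lists also lost their call without the 4 libraries of highest LHY, a run that leaves 1 DPB2oe12.1.5 library. With the clock score as covariate on all 12 libraries, they kept it at the preset correlation (adjusted p = 0.00841 and 0.00198). The DNA damage list kept its call in both runs, though its genes too moved with the first principal component, on which 2 of the 3 DPB2oe12.1.5 libraries and no Col-0 library stood apart.

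Of 7 seed storage genes, PAP85 and EM6 rose, and 7 rose when adjusted over the list alone (median 3.51, adjusted p = 0.00011, but adjusted p = 0.237 with an estimated correlation). Of 8 heat shock genes 0 were called, and 4 rose when adjusted over the list alone (median 1.64, adjusted p = 0.00156, but adjusted p = 0.237 with an estimated correlation). The photosynthesis list had a median of -0.32 with 0 of 18 called, also over the list alone (adjusted p = 0.00257, but adjusted p = 0.346 with an estimated correlation). These 3 lists moved with the first principal component and lost their call without the 4 libraries of highest LHY. That run was chosen after the data were seen and leaves 1 DPB2oe12.1.5 library, assumed to vary like the other groups. With the clock score as covariate, also chosen after the data were seen, all 3 kept their call at the preset correlation (adjusted p = 0.000685, 0.00646 and 0.000685).

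Small shifts were found in 4 further lists, none with a called member. DNA replication had a median of 0.11 (2 rose adjusted over the list alone) and adjusted p = 0.0424, and adjusted p = 0.613 with an estimated correlation. H3.1 and H4 histones had a median of 0.12 (1 rose adjusted over the list alone) and adjusted p = 0.0424, and adjusted p = 0.342 with an estimated correlation. ABA response had a median of -0.26 (0 adjusted over the list alone) and adjusted p = 0.0424, and adjusted p = 0.613 with an estimated correlation. Salicylic acid and defence had a median of -0.40 (1 fell adjusted over the list alone) and adjusted p = 0.0281, and adjusted p = 0.237 with an estimated correlation. None of the 4 passed without the 4 libraries of highest LHY. With the clock score as covariate, DNA replication kept its call (adjusted p = 0.0240), while histones (0.0962), ABA (0.535) and salicylic acid (0.0905) did not. The other 6 lists did not pass (adjusted p from 0.0689 to 0.677).

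The chloroplast genes ATCG00500 (2.58 ± 0.38), ATCG01090 (2.25 ± 0.43) and ATCG01060 (2.22 ± 0.38) were among the largest rises within the naming rule's limits (separate libraries and at least 10 CPM). The share of organelle reads was 1.19 ± 0.356% in DPB2oe12.1.5 and 0.563 ± 0.299% in Col-0, with all 3 libraries above Col-0 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, and 0.225 adjusted over 9 such tests). Besides TGG2, the largest falls within the same limits were in AT1G14250 (-2.72 ± 0.43), AT4G22517 (-1.74 ± 0.30), CDEF1, a cutinase (-1.69 ± 0.23), AT4G22513 (-1.56 ± 0.20) and AT3G05727 (-1.51 ± 0.21). Outside them AT2G47880 fell by -2.75. GL1 did not pass (1.42 ± 0.58, adjusted p = 0.249).

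The 85 calls fell by over 1.5 times without Col-0 replicates 2 and 3 (27 and 15) and without DPB2oe12.1.5 replicates 1 and 2 (23 and 20), and FLC and ATCG01090 lost their calls in all 6 such runs, while 7 of the 19 named genes called kept theirs in all 6 (DPB2, SMR7, BRCA1, AT4G22513, MIOX4, CDEF1 and TGG2). Calls of the DNA replication, histone, ABA and salicylic acid lists ended with 4, 4, 3 and 4 of the 6 libraries left out, and that of the flowering list without DPB2oe12.1.5 replicate 3 (adjusted p = 0.0741).

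The calls against Col-0 overlapped between genotypes. The DPB2oe lines shared 15 rises and 7 falls, DPB2oe1.11.5 and abo4-1 shared 19 rises and 3 falls, and DPB2oe12.1.5 and abo4-1 shared 17 rises and 6 falls, with 0 genes called in opposite directions. Independent lists would share 0.0703 to 0.239 genes. Unchanged groups, simulated with Col-0 libraries in common and genes drawn independently, shared at most 1 rise and 0 falls. Such groups give few calls and hold no structure common to many genes. Their overlap is therefore low by construction and does not measure the part owed to Col-0. Over all genes, the log2 fold changes of these pairs correlated at 0.486, 0.389 and 0.431, no more than in those simulated groups (0.489, 0.493 and 0.483). Their covariances of 0.119, 0.0781 and 0.0994 were above the simulated 0.0548, 0.0551 and 0.0553. That excess may hold what the pairs share beyond the Col-0 libraries, any shared time of day included. It may also hold deviations of the Col-0 libraries common to many genes, which the simulation lacks, so neither part is measured. In all 3 genotypes 11 genes rose, among them BRCA1, PARP2, SMR7, GMI1, XRI1, TK1a, AT5G60250, AT4G22960 and SIP4, and AT2G47880 fell. Since the 3 comparisons share 3 Col-0 libraries, too few to split, the part of each overlap owed to them was not separated.

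Direct tests between the mutants asked which effects differed. Of 30 DNA damage genes, 9 were lower in DPB2oe1.11.5 than in abo4-1 and 4 in DPB2oe12.1.5, or 17 and 11 when adjusted over the list alone, and the rest did not pass. The list medians were -0.67 and -0.49 (adjusted p = 8.67e-12 and 2.19e-13, but 0.0889 and 0.0611 with an estimated correlation). Relative to abo4-1, PARP2 had log2 fold changes of -1.35 ± 0.17 in DPB2oe1.11.5 and -1.62 ± 0.17 in DPB2oe12.1.5, and GMI1 of -1.27 ± 0.17 and -1.32 ± 0.17. SMR7 and BRCA1 were lower in DPB2oe1.11.5 (-2.12 and -0.79) but did not pass in DPB2oe12.1.5 (-1.12 and -0.54, adjusted p = 0.0664 and 0.0999). Besides DPB2, AT5G33370 was higher than in abo4-1 by 5.80 ± 0.33 in DPB2oe1.11.5 and 5.81 ± 0.33 in DPB2oe12.1.5, and MRD1 was lower, at -6.07 ± 0.47 and -6.33 ± 0.50. Between DPB2oe1.11.5 and abo4-1, 327 genes were called (72 higher and 255 lower in DPB2oe1.11.5). AT5G33251 (8.73 ± 0.76) was the largest rise within the naming rule's limits, and U3D (-3.04 ± 0.36) and AT1G11070 (-2.91 ± 0.37) were among the falls. Between DPB2oe12.1.5 and abo4-1, 142 were called (74 higher and 68 lower in DPB2oe12.1.5), with MIOX4 (5.78 ± 0.49) among the rises and AT1G11070 (-3.88 ± 0.41) and AT5G60250 (-2.57 ± 0.28) among the falls. Leaving out 1 library moved the 327 calls to 79, 572 and 82 without DPB2oe1.11.5 replicates 1, 2 and 3 and to 119 and 91 without abo4-1 replicates 1 and 3. It moved the 142 calls to 63, 50 and 91 without DPB2oe12.1.5 replicates 1, 2 and 3 and to 52 and 49 without abo4-1 replicates 1 and 3.

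The DPB2oe lines differed from each other in 6 genes, with 3575 at an unadjusted p under 0.05. In DPB2oe12.1.5 relative to DPB2oe1.11.5, AT1G30870 was higher (1.60 ± 0.21), and AT5G33251 (-6.73 ± 0.64) and TGG2 (-1.39 ± 0.14) were lower, 3 genes being higher and 3 lower in all. Without DPB2oe1.11.5 replicate 2, the library with the highest LHY level, 1119 genes were called, and 20 and 11 without DPB2oe12.1.5 replicates 2 and 3, and 3 without DPB2oe1.11.5 replicate 1 or 3. DESeq2 called 645 genes for the same comparison.

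The 10 most abundant genes took 16.4 ± 0.325% of reads in Col-0, 11.1 ± 0.424% in DPB2oe1.11.5, 11.7 ± 2.11% in DPB2oe12.1.5 and 15.4 ± 3.21% in abo4-1. Both DPB2oe lines lay below Col-0 in all libraries (two-sided exact permutation p = 0.1 for each, 0.225 adjusted). No window of 1 Mb (121 windows) or 2 Mb (62 windows) held more called genes than the tested genes gave by chance after adjustment. The lowest adjusted p was 0.0589, for DPB2oe1.11.5.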

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

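The tests chosen only after their result was seen were those of harvest time for the main axis and for photosynthesis, of a gl1 background, and of the share of green tissue, together with the list tests between mutants. The genes and lists given here were picked out by a direct test of the difference between 2 mutants, which equals the difference between their effects against Col-0. Most of these genes had been named for changes against Col-0 in the same libraries, which favours a difference, so their number is no independent support. Over all 19924 genes, 6 were called between the DPB2oe lines, and 327 and 142 for DPB2oe1.11.5 and DPB2oe12.1.5 against abo4-1.

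The first pattern is that 4 libraries (DPB2oe1.11.5 replicate 2, DPB2oe12.1.5 replicates 1 and 2 and abo4-1 replicate 2) lay apart from the other 8 on the first principal component. Sequencing depth is argued against as the cause, since 4 of the 8 others had counted reads within the range of these libraries (12205407 to 19595776), and so are chloroplast transcripts, since 7 of the 8 others had chloroplast shares within their range. Harvest at different times of day may explain it: the loadings of the clock genes lay at percentile 100 of 10000 random lists, with 4 of 4 morning genes positive and 6 of 6 evening genes negative. Of the other 16 lists, 8 lay above percentile 95, among them seed storage and heat shock (100 each), flavonoid (99.99), ABA (99.89), photosynthesis (99.2) and DNA damage genes (98.2), so differences of developmental stage between libraries stay open as well. Genotype alone is argued against as the cause by the scores of 2 genotypes in replicate order. These were -30.6, 36.9 and -26.8 in DPB2oe1.11.5 and -14.9, 37.0 and -36.4 in abo4-1. The scores of DPB2oe12.1.5 (49.7, 50.3 and 2.36) all lay above those of Col-0 (-6.37, -31.7 and -29.5). A part played by genotype is not separated from harvest time or developmental stage, since no Col-0 library was among the 4.

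The second pattern is a set of 29 genes that changed at least 4-fold in abo4-1, 17 up and 12 down, among 42 that differed there from all 3 other genotypes. A single 1 Mb segment that differs from Col-0 is argued against as the source of most of these genes. At most 2 of the 42 lay in 1 window of 1 Mb, and 0 windows had an excess. With so few genes per window, a segment that alters only a few of them could not be seen. A gl1 background of the abo4-1 line could account for GL2 and some others, and cannot be told apart from an effect of the POL2A allele: the trichome list, which holds GL2, had a median of -0.60 (camera p = 7.03e-05, but p = 0.0532 with an estimated correlation), and its 10 genes outside the pattern also -0.60 (camera p = 0.0056 and 0.169 in the same order), while GL1 was lower by a ratio of 4.84 without passing its test (adjusted p = 0.424), so that the condition written for this explanation (a ratio of at least 3 and a camera p under 0.05) was met, and the stricter reading was adopted after the result was seen. A response shared with the DPB2oe lines cannot be told apart for the set as a whole. The larger median of the signed log2 fold changes there, 0.42, comes from genes chosen for differing between the genotypes, which keeps it low by construction. Of this set, TK1a, PARP2, GMI1, XRI1, AT4G22960 and AT5G60250 were also called as risen in both DPB2oe lines against Col-0, so their rise was shared in part. The other members were not called in the abo4-1 direction in both lines. An effect of the POL2A allele itself stays open and was not tested.

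The third pattern is the lower photosynthesis list in DPB2oe1.11.5. Harvest at different times of day as the whole cause is argued against by the 2 DPB2oe1.11.5 and 2 Col-0 libraries of low LHY, in which the list median was -0.77 and 18 of 18 members were lower. A smaller share of green tissue cannot be told apart from other causes: the root markers had a median of -0.51, under the bound of -0.2 first set against this cause but within the spread of their members (SD 0.79, 4 of 17 higher), and that list did not pass with an estimated correlation (adjusted p = 0.107). An effect of DPB2 overexpression may remain as a hypothesis; it was not tested, and the photosynthesis list did not pass with an estimated correlation (adjusted p = 0.0934).

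Other splits of the 6 libraries of each comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. DPB2oe1.11.5 against Col-0 gave 141 genes, with 0 as the highest of the other splits, so that 1 split was as large. For DPB2oe12.1.5 against Col-0 the values were 85, 0 and 1, for abo4-1 against Col-0 156, 7 and 1, and for DPB2oe1.11.5 against abo4-1 327, 0 and 1, in the same order. In this last comparison, where the rule for pairing was met, all 3 other splits that part as many pairs of the same number gave 0 genes. DPB2oe12.1.5 against DPB2oe1.11.5 gave 6 genes and another split 91, so that 2 splits were as large. DPB2oe12.1.5 against abo4-1 gave 142 genes and another split 595, so that 2 splits were as large. In both cases that other split set the libraries of high LHY against the rest, which points to a structure of the samples.

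For DPB2oe12.1.5 relative to DPB2oe1.11.5, 3 of the genes named against Col-0 or as list members differed in the direct test, with adjusted p from 0.00178 to 0.0114 (log2 fold changes follow). Higher among these were EM6 (2.996). Lower among these were AT5G33251 (-6.73) and TGG2 (-1.39). The list medians that differed were DNA replication (-0.16, adjusted p = 0.0014), G2/M cell cycle (-0.33, adjusted p = 2.87e-05), photosynthesis (0.35, adjusted p = 0.00498) and root tissue markers (0.81, adjusted p = 1.72e-05). Further ones were seed storage (2.26, adjusted p = 0.000179). With an estimated correlation, none of these 5 lists passed (adjusted p from 0.314 to 0.605). AT1G30870 (1.60), named only for this comparison, was higher too.

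For DPB2oe1.11.5 relative to abo4-1, 35 of the genes named against Col-0 or as list members differed in the direct test, with adjusted p from 4.21e-07 to 0.0426 (log2 fold changes follow). Higher among these were AT5G33251 (8.73), DPB2 (4.81), MIOX4 (3.93), AT2G33850 (3.23), MAF5 (2.81), ESM1 (2.06), MAF4 (1.73) and FLC (1.72). Also higher were PRP2 (1.69), GL2 (1.69), CYP86A4 (1.53), AT5G35935 (1.24), AT4G22513 (0.89) and TGG2 (0.80). Lower among these were MRD1 (-6.07), U3D (-3.04), AT1G11070 (-2.91), AT5G60250 (-2.69), SMR7 (-2.12), HCHIB (-2.00), HDA18 (-1.94) and EXPA7 (-1.77). Also lower were SEP3 (-1.70), AT1G67865 (-1.67), AT3G61980 (-1.56), AT5G44550 (-1.48), POLD4 (-1.46), TK1a (-1.36), PARP2 (-1.35) and GMI1 (-1.27). Further negative values were those of CCH (-1.24), XRI1 (-1.18), DMC1 (-0.96), BRCA1 (-0.79) and CDKB2;1 (-0.70). The list medians that differed were Pol epsilon subunits (0.10, adjusted p = 0.045), DNA damage response (-0.67, adjusted p = 8.67e-12), G2/M cell cycle (-0.14, adjusted p = 0.0284) and meiotic recombination (-0.65, adjusted p = 0.014). Further ones were photosynthesis (-0.62, adjusted p = 1.13e-05) and root tissue markers (-0.30, adjusted p = 0.00525). With an estimated correlation, none of these 6 lists passed (adjusted p from 0.0889 to 0.681). The Pol epsilon list holds the overexpressed DPB2, without which it did not pass (adjusted p = 0.987). AT5G33370 (5.80), named only for comparisons with abo4-1, was higher too.

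For DPB2oe12.1.5 relative to abo4-1, 30 of the genes named against Col-0 or as list members differed in the direct test, with adjusted p from 4.09e-07 to 0.0448 (log2 fold changes follow). Higher among these were MIOX4 (5.78), DPB2 (4.83), GL1 (3.57), AT2G33850 (3.54), PAP85 (2.86), ATCG00500 (2.59), ATCG01090 (2.57) and FLC (2.33). Also higher were ATCG01060 (2.16), MAF5 (2.13), GL2 (2.08), MAF4 (1.86), ESM1 (1.70), PRP2 (1.66), CYP86A4 (1.57) and AT5G35935 (1.15). Lower among these were MRD1 (-6.33), AT1G11070 (-3.88), AT5G60250 (-2.57), HDA18 (-2.12), SEP3 (-2.05), PARP2 (-1.62), CDEF1 (-1.58) and HCHIB (-1.35). Also lower were GMI1 (-1.32), DMC1 (-1.11), XRI1 (-1.11), POLD4 (-1.03), CYCB1;4 (-0.97) and TK1a (-0.94). The list medians that differed were DNA damage response (-0.49, adjusted p = 2.19e-13), DNA replication (-0.20, adjusted p = 0.0016), G2/M cell cycle (-0.53, adjusted p = 8.43e-12) and meiotic recombination (-0.92, adjusted p = 1.3e-05). Further ones were ABA response (-0.46, adjusted p = 0.0272), salicylic acid and defence (-0.35, adjusted p = 0.0352), seed storage (2.15, adjusted p = 0.0016) and heat shock (0.82, adjusted p = 0.0243). With an estimated correlation, none of these 8 lists passed (adjusted p from 0.0611 to 0.529). AT5G33370 (5.81), named only for comparisons with abo4-1, was higher too.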

How the results depend on the processing

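Tests chosen only after the result was seen were the clock score covariate, the run without the 4 libraries of highest LHY, the block in the list tests between mutants and the Pol epsilon list without DPB2. With RLE or upper-quartile scaling, a mean of at least 1 CPM or organelle genes removed, the calls in all 6 comparisons stayed within 1.5 times of the reported counts. Counts below are in the order DPB2oe1.11.5, DPB2oe12.1.5 and abo4-1 against Col-0, DPB2oe12.1.5 against DPB2oe1.11.5, and DPB2oe1.11.5 and DPB2oe12.1.5 against abo4-1, and the cause was not tested unless given. DESeq2 called 601, 709, 302, 645, 909 and 609 genes, which held every gene called by edgeR. At a threshold of 0.01 the counts were 32, 13, 62, 83 and 38, all but those between the DPB2oe lines, and shared calls were 7, 9 and 7. Against a 1.5-fold change (glmTreat) they were 22, 8, 49, 60 and 31, in the same comparisons. POL2A in DPB2oe1.11.5 (0.84) lost its call at both. With no filter, which adds genes to the test, the counts were 215 and 180 for the DPB2oe lines against Col-0, 115 between them and 222 for DPB2oe12.1.5 against abo4-1. With only the 2 groups compared, which are fewer libraries, all but DPB2oe12.1.5 against Col-0 moved, to 221, 99, 1, 103 and 43.

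The replicate number as a block was fitted to all 12 libraries, although the rule for pairing was met only by DPB2oe1.11.5 and abo4-1, where it gave 422 calls and all 35 genes and 6 lists given for this comparison kept theirs. In the other 5 pairs of groups, which share only numbers, at least 1 of the 3 correlations of deviations was 0.1 or lower. Over all 18 pairs of the same number the mean was 0.119, against -0.0600 for other pairs, and 7 of 12 libraries correlated best with their own number, which is a hint from the data and not from the design. With the block, DPB2oe12.1.5 gave 152 calls against Col-0 and 17 against DPB2oe1.11.5. The DNA replication and histone lists of DPB2oe12.1.5 (adjusted p = 0.0601 for each) lost their call against Col-0, as did FLC and ATCG01090 there, SEP1 in abo4-1 and GL1 for DPB2oe12.1.5 against abo4-1 (0.0542). The heat shock list passed in DPB2oe1.11.5 (0.0336), and the photosynthesis (0.0423) and flavonoid (0.0292) lists passed in abo4-1. The block changed no other call of a named gene or list against Col-0, and ended no other one given between mutants.

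With the clock score covariate, DPB2oe1.11.5 against Col-0 gave 573, DPB2oe12.1.5 against DPB2oe1.11.5 gave 104 and DPB2oe1.11.5 against abo4-1 gave 920. Without the 4 libraries of highest LHY, DPB2oe12.1.5 keeps 1 library, assumed to vary like the others, and the counts other than that of abo4-1 against Col-0 were 925, 47, 1042, 1065 and 74. In that run 3 lists passed for DPB2oe12.1.5 against Col-0, and the DNA replication list turned its direction there (adjusted p = 0.270). The DNA damage list passed in all 3 comparisons with Col-0 in both runs with the preset correlation, and an estimated one was not tried in them. With an estimated correlation, 4 lists passed in DPB2oe1.11.5, the Pol epsilon list with its overexpressed DPB2 among them, and 0 in DPB2oe12.1.5. With fry, 4 passed in DPB2oe12.1.5 (Pol epsilon, DNA damage, G1/S and flowering). The lists called in abo4-1, and those called in DPB2oe1.11.5 other than ABA response, kept their call with fry. Without DPB2, the Pol epsilon list passed camera in none of the 3 comparisons with Col-0 (adjusted p = 0.213, 0.525 and 0.0886). Fry gave it unadjusted p values of 0.00844, 0.149 and 0.00574 in the same order.

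With each library left out in turn, the counts ran from 21 to 286, 15 to 95, 65 to 94, 3 to 1119, 79 to 572 and 49 to 207, and the lists called against Col-0 from 8 to 10, 7 to 10 and 6 to 12. Shared calls ran from 9 to 32 for the DPB2oe lines, 8 to 26 for DPB2oe1.11.5 and abo4-1, and 8 to 33 for DPB2oe12.1.5 and abo4-1. POL2A ran from 0.76 to 0.98, 0.16 to 0.51 and 0.59 to 0.66 against Col-0, and GL1 from -0.11 to 0.57, 1.05 to 1.74 and -3.07 to -1.74. DPB2 ran from 5.06 to 5.59, 5.07 to 5.60 and 0.23 to 0.76 against Col-0, and from 4.71 to 4.93 and 4.72 to 4.94 against abo4-1. With this number of libraries, depth and spread, 1.5-fold changes were recovered in 2.99% of simulated genes at most, and depth was not varied alone.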

Other observations

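Apart from AT5G33370, named by rule for the comparisons with abo4-1, the genes in this part were chosen after their values were seen. AT5G33370 (log2 fold change -5.33), GLC (-4.73) and CYP86A7 (-3.30) were lower in abo4-1 than in Col-0. SHN2, a transcription factor gene, had 2 counts in abo4-1 and 50 in Col-0, a ratio of 18.8 (95% counting interval 4.95 to 160).

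Other genes lost or gained nearly all their reads in 1 genotype. ZIP7 (AT2G04032) had 0 counts in abo4-1 and 104 in Col-0, at least 26.1-fold lower against a floor of 3 counts over the group, and AT1G06100 had 0 and 90 counts, at least 22.6-fold lower. AT3G55920 had 303 counts in abo4-1 and 3 in Col-0, a ratio of 134 (45.5 to 654). In DPB2oe1.11.5, AT2G05030 had 73 counts against 0 in Col-0, at least 24.1-fold higher, and its neighbour AT2G05040 had 342 against 13. AT5G07610 was near 0 in Col-0 with 2 counts and had 174, 101 and 116 counts in DPB2oe1.11.5, DPB2oe12.1.5 and abo4-1, ratios of 86.2 (23.5 to 718), 71.5 (19.3 to 599) and 77.0 (20.8 to 643).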
